A study of Homo sapiens with 12 samples.

How the data were processed

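Genomic DNA of 12 MOLM13 libraries was amplified and sequenced for guide RNAs, per the labels. The deposited table gives whole-number counts of reads per guide, with a guide name, a target name and 12 count columns. The submitters' processing notes name MAGeCK 0.5.6 and the hg38 build; how reads were matched to guides is not given in the sources used here. The authors' counts are not normalized, and 0 columns of per-sample values were left unused. PCR reads carry no molecular identifiers here. Intervals given below resample or count guides or pseudo-targets of these libraries, and do not cover variation over further libraries.

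Samples were grouped by the labels into early and late proliferation, venetoclax and its DMSO control, and ATRA and its DMSO control, with 2 replicates each. The labels do not say that replicates came from separate cultures, so guide p-values measure only the spread between these libraries, which may be technical. Target p-values compare the ranks of a target's guides with random draws, so guides and not libraries are the units there. List and overlap tests likewise run over guides or targets. The batch entry of each sample's labels holds its replicate number, and this was taken to pair samples; no shared culture or day is given. The deviations of same-numbered libraries correlated at 0.0561 in proliferation, 0.215 in venetoclax and 0.0724 in ATRA. The fit reported had no block, and the replicate block was an alternative. A permutation test of 2 against 2 libraries cannot reach the threshold, so guide p-values rest on models fitted across guides.

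Each screen was fitted on its own 4 libraries, with 2 residual degrees of freedom, in edgeR 4.0.16 (limma 3.58.1, R 4.3.3). Guides were kept by filterByExpr with a minimum count of 10, scaled by TMM and tested with edgeR's quasi-likelihood test. One-sided guide p-values were ranked, and targets with 3 or more tested guides were scored by robust rank aggregation with alpha 0.25. Their p came from 1000000 random draws, so the smallest possible p is 1e-06, and was adjusted by Benjamini-Hochberg per direction with a threshold of 0.05. Log2 fold changes of a target are medians over its guides, and replicate pair values used a prior count of 2. Lists fixed beforehand were tested over guides with camera at a preset correlation of 0.01 and at an estimated one, adjusted within a screen. Guides of 1 target counted as separate members there, so 1 strong target can carry a list. The core essential protein and HOX cluster lists had 0 targets in the library, and lists of fewer than 3 testable targets were not tested with camera. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for the rest.

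The rule for named targets, the lists, tests and alternatives were set before the data were examined. Per screen and direction, named targets were the 10 with the largest median among those past the threshold in the same direction in both replicate pairs, or the 5 with the smallest p where fewer than 5 passed. Passing list members, up to 4 per list, and BCL2 were also named; ITGAM, BAX, MYC, FLT3 and RARA are not targets here. A further target that the rule names is not reported here and is not drawn in the figures, and counts over all targets include it. List members named because they passed only when adjusted over the list alone were chosen after their values were seen. Names were matched to RefSeq GRCh38.p14 by symbol or synonym on the guide name's chromosome, which placed 414 of 7430 targets. Guide sequences and positions were not used here, so a guide's distance to a promoter is unknown.

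Alternatives were the replicate block, DESeq2 size factors, scaling on NONT guides, no filter, a minimum count of 50, all 12 libraries in 1 fit, DESeq2 1.42.0 (Wald test), each library left out, counts summed per target, alpha 0.1, 5 or more guides and a threshold of 0.25. A left-out library leaves 1 library in its arm, assumed to vary like the others. The method was tested on simulated counts with 200 of 7565 targets changed. All guides of a changed target were given the same fold change, so recovery of targets with uneven guides was not tested. In the proliferation simulation 50 of 50 targets lowered 1.5-fold were recovered with 1 false call, and in the venetoclax simulation 50 of 50 with 2 false calls. Of targets raised 1.5-fold, 50 of 50 were recovered in proliferation and 46 of 50 in venetoclax. The chi-square of replicate libraries per degree of freedom ran from 2.56 in the early to 112.6 in the ATRA group, so no 2 libraries agreed within sampling noise. Guides under 10 reads numbered 16 to 71 in the proliferation and venetoclax libraries and 803 to 3888 in the ATRA screen.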

Results

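Guide RNA abundance was read from genomic DNA of MOLM13 cells, a human acute monocytic leukaemia line, carrying a pooled library for CRISPR interference. In this method a catalytically dead Cas9 fused to the KRAB repressor silences transcription at the site each guide matches. The 12 libraries formed 6 groups of 2 replicates in 3 screens. The proliferation screen set late against early cells. The venetoclax screen set drug-treated against DMSO-treated cells, and the cells of this screen were sorted for the BFP-tagged repressor. The all-trans retinoic acid (ATRA) screen set ATRA-treated against DMSO-treated cells, sorted for the surface marker CD11b. The labels give neither doses nor days, and do not say which CD11b gate was kept. Total counts ran from 17520391 to 25789735 reads per library, with a median of 349 to 509 reads per guide. The table holds 46188 guides for 7730 targets, and 7650 of these targets have 6 guides. Most of the library, 5582 targets, carries CATG identifiers of unnamed loci, beside named long non-coding RNAs and a few protein-coding genes. The 150 target names starting with NONT have no genome position and were taken as negative controls, which the table does not spell out.

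The proliferation comparison asked which targets changed the share of cells carrying their guides between the early and late time points. Guides against SPI1, which encodes the myeloid transcription factor PU.1, fell most among the named targets. Their median log2 fold change was -2.62, with -2.88 and -2.40 in the 2 replicate pairs, and their summed level went from 94.2 ± 0.2 to 19.8 ± 0.5 counts per 1000000 reads (CPM; SD, n = 2). RP11-444A22.1 fell by 2.42 on the log2 scale, LINC00886 fell by 1.96, and MIR17HG, the host transcript of the miR-17-92 microRNA cluster, fell by 1.12. All 6 guides of each of these 4 targets were depleted singly.

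In all, 20 of 7565 tested targets were depleted and 1 was enriched at an adjusted p under 0.05 (edgeR's quasi-likelihood test on guides, robust rank aggregation per target, Benjamini-Hochberg adjustment). SPI1, RP11-444A22.1, LINC00886 and MIR17HG each had an adjusted p of 0.00108 by edgeR and rank aggregation. Of the unnamed loci, CATG00000039091.1 had a median log2 fold change of -1.17, CATG00000000618.1 -0.94, CATG00000020473.1 -0.89, CATG00000006264.1 -0.85 and CATG00000056789.1 -0.64. SNHG12, a host of small nucleolar RNAs, fell by 0.60. BCL2, the antiapoptotic protein that venetoclax inhibits, fell by 0.48, and TERC, the telomerase RNA, fell by 0.36. UHRF1, chosen after its value was seen, fell by 0.35. CATG00000035012.1, also chosen after its value was seen, was called although its median was -0.03, since 2 of its 6 guides carried the call. Without late replicate 1 the depleted count was 13, and BCL2 at -0.46, TERC at -0.39, CATG00000056789.1 at -0.47, UHRF1 at -0.27 and CATG00000035012.1 at 0.02 were among those that lost their calls. SNHG12, at -0.44, TERC, at -0.36, and CATG00000035012.1, at -0.14, lost theirs without late replicate 2. TERC, at -0.38, and CATG00000035012.1, at -0.0058, lost theirs without early replicate 1, and UHRF1, at -0.26, without early replicate 2. The enriched count was 4 without early replicate 1 and 2 without late replicate 2. The next enriched targets by p did not pass: CATG00000057427.1 at 0.22, CATG00000104192.1 at 0.14, CATG00000002239.1 at 0.29 and CATG00000011386.1 at 0.23. CATG00000057427.1 passed without early replicate 1, at 0.27.

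**Figure D1:**
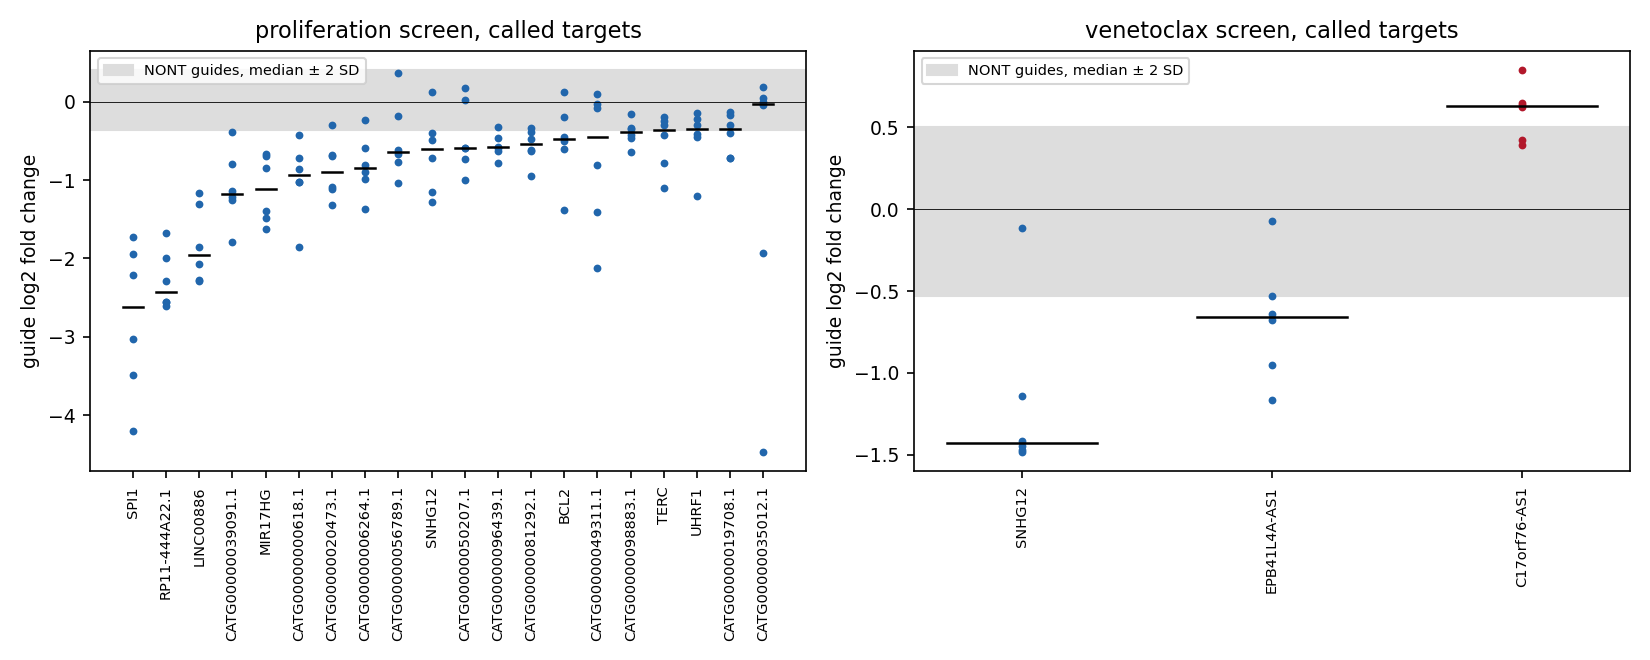
Log2 fold change of each guide (points, vertical axis) for the called targets shown (horizontal axis) in the proliferation and venetoclax screens, with the median of each target as a black line and the median of NONT guides ± 2 SD as a grey band. All 6 guides of SPI1, RP11-444A22.1, LINC00886 and MIR17HG lie outside it in the proliferation screen.

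The called genes have known places in GRCh38.p14. SPI1 lies on chromosome 11 from 47354860 to 47378547, and BCL2 on chromosome 18 from 63123346 to 63320090. LINC00886 lies on chromosome 3 from 156747343 to 156817062, 9291 bp from the protein-coding gene LEKR1. MIR17HG lies on chromosome 13 from 91347687 to 91354577, and its nearest protein-coding gene, GPC5, is 44044 bp away. SNHG12 lies on chromosome 1 from 28578538 to 28582983 and overlaps the protein-coding gene TRNAU1AP. TERC lies on chromosome 3 from 169764610 to 169765060. RP11-444A22.1 matched no symbol in the annotation used here, and the table places it only on chromosome 2.

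Among the lists fixed beforehand, the leukaemia dependency genes had 3 targets, SPI1, BCL2 and RUNX1. SPI1 and BCL2 were depleted over all targets, and 3 of 3 were when adjusted over the list alone, where RUNX1 had a median of -0.09. The list fell as a group (camera adjusted p = 3.27e-28). That test took 18 guides of 3 targets as nearly independent members, and SPI1, at -2.62, lay far below BCL2, at -0.48, and RUNX1. With an estimated correlation the call was lost (camera adjusted p = 0.0562). With the replicate block it was kept at the preset correlation (camera adjusted p = 1.75e-29) and lost at an estimated one (camera adjusted p = 0.359). With the median guide of each target, which leaves 3 guides, it was kept (camera adjusted p = 0.0483 with an estimated correlation). The 12 leukaemia long non-coding RNAs and the 10 microRNA hosts each had 1 depleted member, MIR17HG, and an adjusted p of 0.000833 by camera. The list medians were -0.0350 and -0.0313, against -1.12 for MIR17HG, so a shift of the whole lists is not shown. With an estimated correlation the adjusted p was 0.107 for both. Adjusted over the list alone, 2 of the 12 leukaemia RNAs were depleted, the second being TP73-AS1 at -0.58. The list of small RNA hosts held DANCR, EPB41L4A-AS1, SNHG5, SNHG11, SNHG12 and TERC, which is not itself a host. SNHG12 and TERC were depleted, while the median of the 6 was 0.01 and camera gave an adjusted p of 0.0953 toward lower values. When adjusted over the list alone, 2 were depleted and 1, EPB41L4A-AS1 at 0.21, was enriched. The 6 targets near MYC on chromosome 8 had none depleted and a camera adjusted p of 0.914; adjusted over the list alone LINC00977 was enriched at 0.13. Antisense-type names here are those ending in -AS, -OT or -IT with a number. Of the 80 such targets none was called, and 1 was when adjusted over the list alone (camera adjusted p = 0.914). Those named after essential or leukaemia dependency genes, MYB-AS1, PSMD6-AS2, RRM1-AS1 and SIK3-IT1, are labelled antisense of essential genes below. None of these 4 was called under either adjustment (camera adjusted p = 0.914). Of the 2 differentiation genes SPI1 was depleted and CEBPB, at -0.31, passed only when adjusted over the list alone.

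Single guides were called far more often than targets such as SPI1. At an adjusted p under 0.05 by edgeR's quasi-likelihood test, 1231 of 46169 guides were depleted and 97 enriched. The split moved with the libraries used, to 3291 and 2414 without late replicate 1 and 2715 and 1376 without late replicate 2. None of the 899 NONT guides was called, while 53 of them had an unadjusted p under 0.05. Of the 900 guides of another class, marked nc in the table, which does not give its meaning, 4 were depleted and 1 enriched, and 0 of its 150 targets passed (9 at an unadjusted p under 0.05). Only 68 of the depleted guides, 5.52%, belonged to called targets such as SPI1. Of the 1073 targets with a depleted guide, 957 had exactly 1. Of 149 pseudo-targets of 6 random NONT guides, 0 passed, which allows up to 2.45% (exact binomial, 95%). That limit is above the 0.264% of targets called depleted, so the check cannot vouch for the calls. None of the 149 had an unadjusted depleted p under 0.05 by rank aggregation. NONT guides also spread less than guides of loci (SD 0.191 against 0.318 on the log2 scale).

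**Figure D2:**
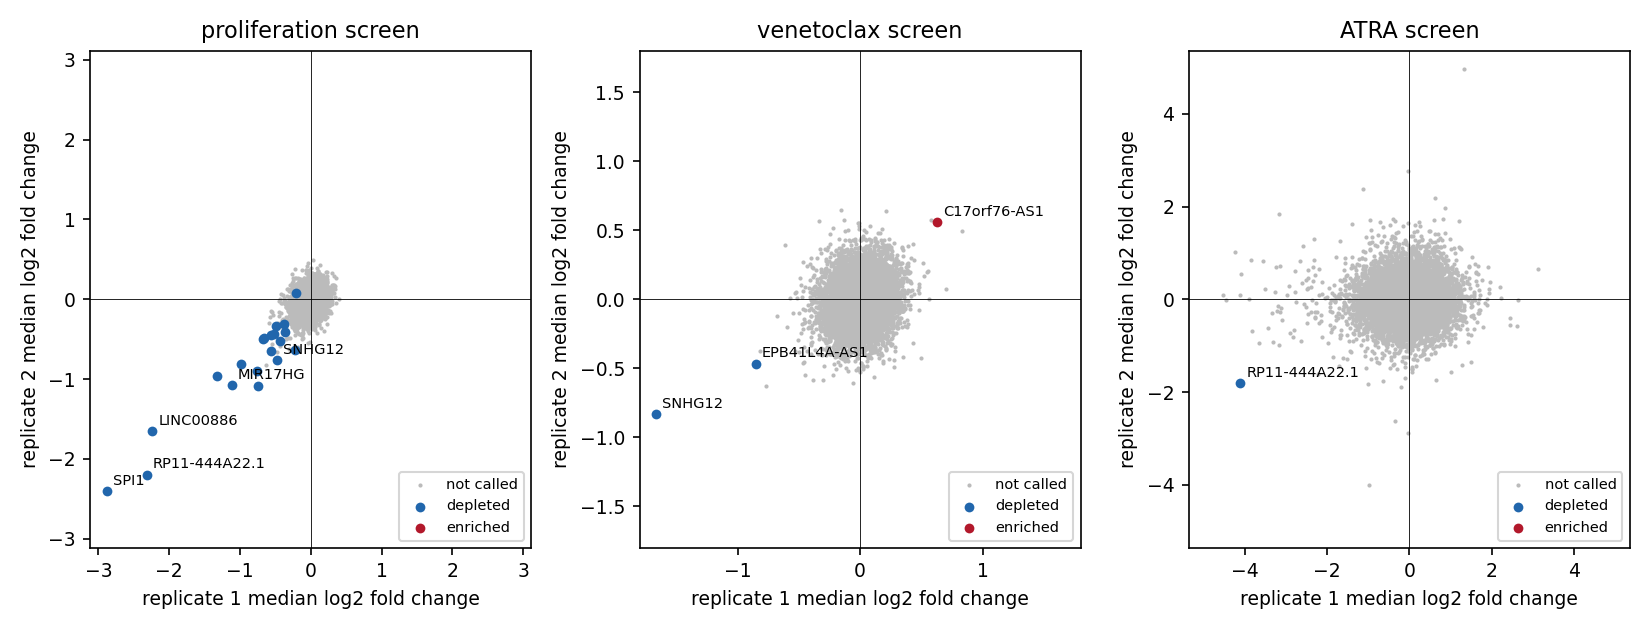
Median log2 fold change of each target in replicate pair 1 (horizontal axis) against replicate pair 2 (vertical axis) for the 3 screens, with the called targets shown in colour. SPI1 at -2.88 and -2.40 and RP11-444A22.1 at -2.32 and -2.20 stand apart in the proliferation screen, and the ATRA screen spreads most.

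The venetoclax comparison asked which targets changed survival or growth under the BCL2 inhibitor. SNHG12 guides fell by a median of 1.43 on the log2 scale, with -1.67 and -0.83 in the replicate pairs. Its 6 guides ranged from -1.48 to -0.11. Their summed level went from 78.8 ± 5.6 to 46.7 ± 9.3 CPM (SD, n = 2). EPB41L4A-AS1, another host of small nucleolar RNA, fell by 0.66, and C17orf76-AS1, now named SNHG29 and of the same kind, rose by 0.63. Few of their guides were called singly: 1 of 6 for SNHG12, 0 of 6 for EPB41L4A-AS1 and 1 of 6 for C17orf76-AS1.

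Among 7565 targets 2 were depleted and 2 enriched, and SNHG12, EPB41L4A-AS1 and C17orf76-AS1 each had an adjusted p of 0.00378 (edgeR's quasi-likelihood test, rank aggregation, Benjamini-Hochberg adjustment). SNHG12 and EPB41L4A-AS1 lost their calls without venetoclax replicate 1, at -1.10 and -0.69, and without venetoclax DMSO replicate 1, at -1.16 and -0.52, leaving 0 depleted targets by edgeR and rank aggregation. C17orf76-AS1, at 0.63, lost its call without venetoclax replicate 1, leaving 1 enriched target. CATG00000056789.1 passed without venetoclax replicate 2, at -0.92. With the replicate as a block, 4 targets were enriched, the added ones being RP11-638I2.6 at 0.67 and CATG00000103230.1 at 0.01, whose block adjusted p by edgeR was 0.0454 in both cases. EPB41L4A-AS1 lies on chromosome 5 from 112160526 to 112162501 and overlaps EPB41L4A. SNHG29 lies on chromosome 17 from 16438987 to 16470648 and overlaps LRRC75A.

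BCL2 had a median of -0.31 and did not pass (edgeR and rank aggregation adjusted p = 0.874). Nor did the next targets by p, CATG00000056789.1 at -0.71, CATG00000042591.1 at -0.49, PVT1 at -0.38 and CATG00000056029.1 at 0.34. The 6 targets of the small RNA host list had SNHG12 and EPB41L4A-AS1 depleted over all targets and 4 when adjusted over the list alone, with TERC at -0.42 and SNHG11, whose median was 0.07. As a group they fell (camera adjusted p = 3.09e-10), and the call was lost with an estimated correlation (adjusted p = 0.251). C17orf76-AS1, a host that was enriched, was not matched to the list under its older name and so was not in this test. The MYC neighbours fell as a group (camera adjusted p = 0.0422), which was lost with an estimated correlation (adjusted p = 0.438) and without venetoclax replicate 1 (median -0.125), venetoclax replicate 2 (median -0.108) or venetoclax DMSO replicate 1 (median 0.0242, camera adjusted p = 0.623). PVT1 and LINC00977, at -0.29, were depleted when adjusted over the list alone. In the leukaemia dependency list 0 of 3 passed over all targets and BCL2 and RUNX1, at -0.18, when adjusted over the list alone (camera adjusted p = 0.311). The leukaemia RNAs and the microRNA hosts had 0 called over all targets and 1, MIR181A1HG at 0.34, enriched when adjusted over the list alone (camera adjusted p = 0.413 for both). Antisense-type names had 1 depleted and 1 enriched, EPB41L4A-AS1 and C17orf76-AS1, and adjusted over the list alone 2 depleted, ADAMTS9-AS1 being the second, and 1 enriched (camera adjusted p = 0.974). The antisense of essential genes had 0 called (camera adjusted p = 0.974), as had the 2 differentiation genes.

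At the guide level 40 of 46148 guides were depleted and 49 enriched by edgeR's quasi-likelihood test, and 0 of 899 NONT guides, of which 28 had an unadjusted p under 0.05. With the replicate block the count of changed guides rose from 89 to 266. The split moved with the libraries used, to 206 depleted and 159 enriched without venetoclax replicate 1 and to 8 and 29 without venetoclax DMSO replicate 1. None of 149 NONT pseudo-targets passed, which allows up to 2.45%. Pseudo-targets were held to the largest p of a called target, here the smallest possible, 1e-06. This outcome was therefore nearly fixed beforehand and cannot vouch for the calls.

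The ATRA comparison asked which targets changed the share of guides in CD11b-sorted cells after ATRA, an inducer of myeloid differentiation. RP11-444A22.1 was the 1 target called, with a median log2 fold change of -2.37, and -4.11 and -1.81 in the replicate pairs (edgeR and rank aggregation adjusted p = 0.0378). Its summed level went from 183.5 ± 4.8 to 40.7 ± 9.9 CPM (SD, n = 2). The call was lost with DESeq2's Wald test, at -2.38, in a fit of all 12 libraries, at -2.37, without ATRA replicate 1, at -1.69, and without ATRA DMSO replicate 2, at -2.25, leaving 0. In the fit reported here its 6 guides ranged from -4.45 to 0.62. With the replicate as a block, 2 targets were depleted, the other being CATG00000019288.1, at -1.91 in the fit without the block.

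BCL2 had a median of -0.38 and did not pass (adjusted p = 0.991 by edgeR and rank aggregation). SPI1 could not be tested, since 4 of its 6 guides were under 10 reads in both ATRA DMSO libraries and 3 in both ATRA libraries. The next depleted targets by p, CTD-2666L21.1 at -0.97, AC064834.2 at -0.80 and CATG00000001331.1 at -1.30, did not pass, nor did the 5 enriched ones, RP11-584P21.2 at 0.89, CATG00000072786.1 at 0.97, CATG00000094661.1 at 0.93, CATG00000006278.1 at 0.84 and KCP at -0.06. With counts summed per target 4 were enriched, among them RP11-584P21.2, at 1.02, and KCP, at 1.56, the latter with 1 of its 6 guides at 2.45. ZSCAN16-AS1, an antisense-type name chosen after its value was seen, was also among these 4. In the fit reported, no fixed list had a called member or passed camera, and the lowest camera adjusted p was 0.871.

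No guide passed edgeR's quasi-likelihood test. An unadjusted p under 0.05 was found for 1081 of 45837 guides, 2.36%, and for 2.13% of NONT guides, less than chance alone gives. DESeq2's Wald test called 549 guides. Replicate libraries correlated at 0.471 in ATRA DMSO and 0.475 in ATRA, against 0.975 in the early and 0.890 in the venetoclax group. In simulated data with this spread, 0 of 200 targets changed 1.5-fold or 2-fold were recovered, 22 of 50 lowered 4-fold and 41 of 50 lowered 8-fold, so changes under 4-fold were mostly not detectable here. None of 148 NONT pseudo-targets passed, which allows up to 2.46%. That limit is above the 0.0132% of targets called depleted, so the check cannot vouch for the call.

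**Figure D3:**
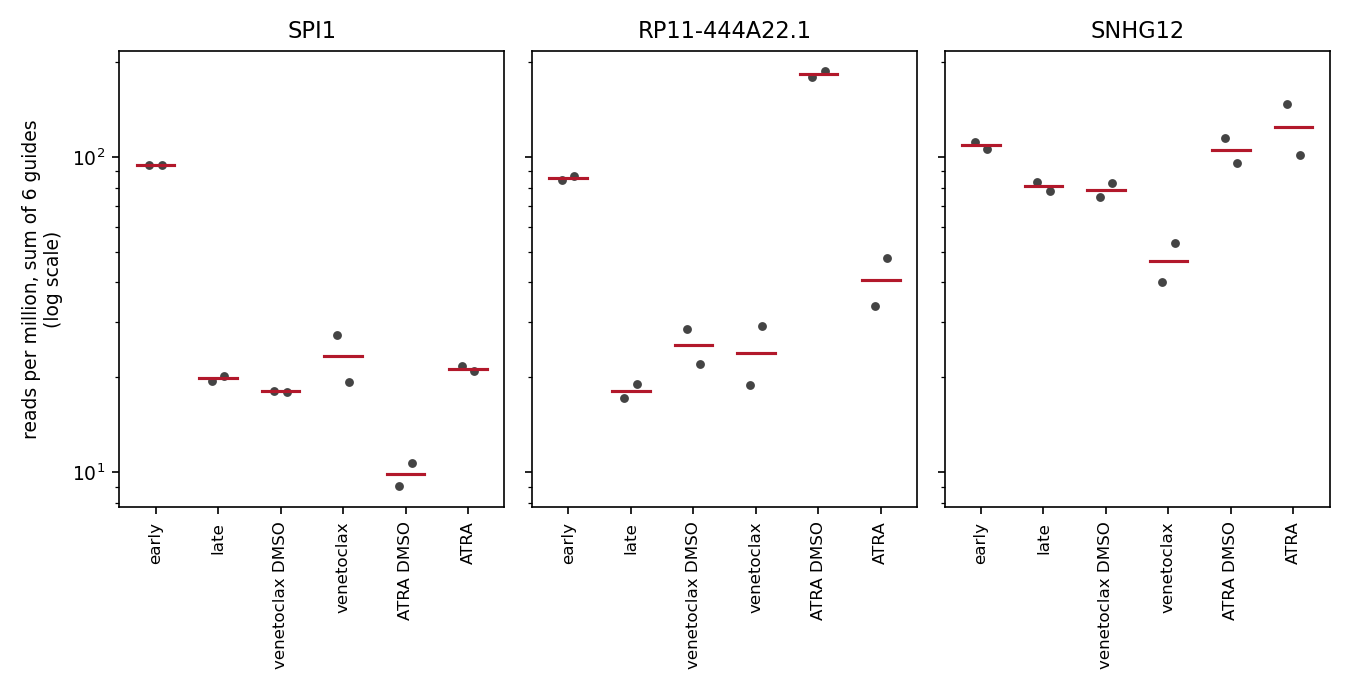
CPM summed over the 6 guides of SPI1, RP11-444A22.1 and SNHG12 (vertical log axis) in each library of the 6 groups (horizontal axis), with the group mean as a red line. RP11-444A22.1 averages 183.5 in ATRA DMSO and 86.0 in the early group.

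Across screens, SNHG12 was depleted in both proliferation and venetoclax, where independent lists share 0.00529 targets (Fisher's exact test, one-sided, adjusted p = 0.0211 over 12 tests of this kind). That overlap is 1 target, and SNHG12 lost its proliferation call without late replicate 2. It lost its venetoclax call without venetoclax replicate 1 or venetoclax DMSO replicate 1. RP11-444A22.1 was depleted in both proliferation and ATRA (Fisher's exact adjusted p = 0.0151). It was the 1 target called in ATRA, and that call was lost with DESeq2's Wald test and other alternatives. Its ATRA DMSO control stood at a median log2 change of 1.14, relative to the early libraries and to NONT guides. The shared call therefore does not show the same loss in both screens. No target was shared by the venetoclax and ATRA calls. The screens share no control library. Median effects of all targets correlated, across targets, which are not independent replicates, at r = 0.098 between proliferation and venetoclax, 0.0795 between proliferation and ATRA, and -0.037 between venetoclax and ATRA.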

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

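Leaving single libraries out of the list tests was chosen after the data were seen; all other alternatives were planned. Of the values for named targets, 526 kept direction and side of the threshold, 12 passed it newly, 16 no longer passed and 6 changed sign. In proliferation SPI1, LINC00886 and RP11-444A22.1 (adjusted p up to 0.00151) and MIR17HG (up to 0.00473) kept their depleted calls under every alternative run (edgeR, DESeq2 or summed counts).

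Counts summed per target gave 280 depleted and 49 enriched in proliferation, 8 and 14 in venetoclax, and 2 and 4 in ATRA; a sum lets 1 strong guide carry a target. Named targets that passed here and not in the fit reported were CATG00000057427.1, CATG00000002239.1 and CATG00000011386.1 in proliferation, CATG00000042591.1, RP11-638I2.6 and TERC in venetoclax, and RP11-584P21.2 and KCP in ATRA. At a threshold of 0.25 the depleted targets were 48 in proliferation and 10 in venetoclax, the enriched ones in venetoclax 5, and 4 were depleted in both screens. Fitted alone, the screens had coefficients of variation between replicates of 0.0943 in proliferation, 0.169 in venetoclax and 0.725 in ATRA. The fit of all 12 libraries uses a single spread per guide for all screens. It called 0 guides in proliferation, 2 in venetoclax and 1164 in ATRA, with 0 ATRA targets. Its 16 depleted proliferation targets kept 13 of 20 calls, without CATG00000056789.1 (-0.64), UHRF1 (-0.36) and CATG00000035012.1 (-0.03) among others; alpha 0.1 kept 18, without UHRF1 (-0.35) and CATG00000019708.1 (-0.35). DESeq2's Wald test called 549 ATRA guides and 0 targets. The replicate block gave 4 enriched venetoclax targets, 266 venetoclax guides and 2 depleted ATRA targets; in proliferation it gave 1871 changed guides against 1328 (265 enriched against 97) and exchanged CATG00000019708.1 for CATG00000042991.1 (chosen after their values were seen), and it changed no other called target. The cause was not tested.

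Without single libraries, depleted targets ranged from 13 to 22 in proliferation, 0 to 4 in venetoclax and 0 to 2 in ATRA; enriched ones from 1 to 4 and 1 to 2; guides from 899 to 5705 (5705 without late replicate 1, 2414 of them enriched; 4091 without late replicate 2, 1376 enriched; 48 and 46 enriched without early replicate 1 and 2) and 37 to 365 (365 without venetoclax replicate 1, 319 without replicate 2, 37 and 47 without DMSO replicate 1 and 2). ATRA had 0 guides throughout.

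List medians over those fits ranged, in proliferation, from -0.0289 to 0.0377 (MYC neighbours), -0.0689 to 0.0416 (small RNA host list) and -0.0539 to 0.0280 (antisense of essential genes). In venetoclax they ranged from -0.0064 to 0.0143 (antisense names), -0.125 to 0.0242 (MYC neighbours), -0.0212 to 0.0698 (leukaemia RNAs), -0.0734 to 0.0741 (microRNA hosts) and -0.0225 to 0.0309 (antisense of essential genes). In ATRA they ranged from -0.0164 to 0.14 (antisense names), -0.31 to 0.0249 (MYC neighbours), -0.16 to 0.14 (leukaemia RNAs), -0.15 to 0.15 (small RNA host list), -0.20 to 0.17 (microRNA hosts) and -0.43 to 0.23 (antisense of essential genes). Under the replicate block the median was -0.0054 for antisense names in venetoclax, and in ATRA 0.0373 for leukaemia RNAs, 0.10 for microRNA hosts and -0.14 for antisense of essential genes. With the median guide of each target, the small RNA host list passed in proliferation (median 0.0126, camera adjusted p = 0.00506) but not with an estimated correlation (adjusted p = 0.349); it also passed without early replicate 2 (0.0385) and without late replicate 1 (0.0406), but not with an estimated correlation (adjusted p = 0.773 and 0.757). With the median guide the MYC neighbours did not pass in venetoclax (median -0.0528, camera adjusted p = 0.272).

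CATG00000103230.1 in venetoclax ranged from -0.0678 to 0.13 without single libraries, BCL2 in ATRA from -0.81 to 0.18 and KCP in ATRA from -0.44 to 0.58; KCP was 0.0177 with the replicate block and 1.56 with summed counts. Replicate pairs correlated across targets at r = 0.382 in proliferation, 0.163 in venetoclax and 0.0384 in ATRA for medians, and at 0.640, 0.213 and 0.0300 for means over guides.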

Other observations

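The test of read depth in the ATRA screen, the shared losses without depleted guides and the rank of RP11-444A22.1 were chosen after the result was seen. RP11-444A22.1 moved in opposite ways in the 2 DMSO arms. Relative to the early libraries and to NONT guides, its median log2 change was -1.64 in the venetoclax DMSO arm, 4th lowest of 7565 targets, with 0 of 6 guides higher. In the CD11b-sorted ATRA DMSO arm it was 1.14, 2nd highest of 7565, with 5 of 6 guides higher. Its lower level under ATRA was therefore measured against a raised control. No test of the difference between arms was run, and the arms differ in sort and handling.

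The depletion seen in the proliferation screen was also read in the DMSO libraries of the other screens. The labels do not say whether these cells came from the same parent culture, and venetoclax DMSO replicate 1 correlated with late replicate 1 at 0.936, near the 0.939 between the late replicates. The 22 targets called without early replicate 2 had a median log2 change of -0.77 from that library to the venetoclax DMSO arm, and 22 of 22 were below 0. In that arm SPI1 stood at -2.41, LINC00886 at -1.72 and MIR17HG at -1.06. In the ATRA DMSO arm 17 of 22 were below 0. Of the 20 targets depleted in proliferation, 14 had a lower and 6 a higher median under venetoclax, with a median of -0.14. SPI1, at 0.41, MIR17HG, at 0.13, and LINC00886, at 0.09, were among the 6 higher, and this split was not tested.

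Most depleted guides of the proliferation screen stood alone in their target. Chance spread between the 4 libraries is argued against: 681 such guides, called without early replicate 2, had a median log2 change of -1.58 from that library to the venetoclax DMSO arm (bootstrap interval -1.64 to -1.51). Few reads are argued against too, with a median of 438 early reads against 446.5 over all guides. A shift of 0.05 or more in the median of the other guides is argued against. Their median lay below that of guides in targets with no called guide, but by less than 0.05 (difference -0.00804, bootstrap interval -0.0142 to -0.00144). These guides were by selection not called depleted, and a median over 4771 guides cannot show an effect in a minority of targets. A weaker target effect in some of these targets therefore stays open. Drift inherited from a shared parent culture was not tested and may remain. So may guide-specific effects, such as off-target binding or 1 effective guide per target, which need the guide sequences, which were not used here.

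The ATRA screen varied most between replicates. Read depth is argued against: the venetoclax DMSO libraries had fewer reads, yet NONT guides differed between replicates 3.22 times as much in the less spread ATRA group (bootstrap interval 2.97 to 3.40), where counting error gives up to 1.03. Few cells per guide after sorting stays open. Among guides above the median early count, 14 were lost in both replicates, 15.2 times the number that loss at 1 chance for every guide gives (interval 8.32 to 25.5), a bound set beforehand at 2 times. The bound was therefore exceeded. It took every guide to be lost with the same chance, yet 3 of the losses in ATRA DMSO and 7 in ATRA were of guides depleted in proliferation. Those guides do not account for all of the excess. Without them 4 losses remained, 10.3 times the number (interval 2.82 to 26.5), still above the bound. The remaining guides may also differ in their chance of loss, so the test cannot decide. Losses in single libraries were far more, 99 and 61 in ATRA DMSO and 489 and 31 in ATRA, and no biological explanation was tested.

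Consecutive targets in library order, which follows chromosome position, correlated weakly. In venetoclax r was 0.0186, just under the 0.0192 that 95% of shuffled orders stay below (permutation p = 0.0557), and in proliferation it was 0.0249 (permutation p = 0.0175). Both screens had been required to pass, so chance order is not excluded and may account for the pattern.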
